A study of Mus musculus with 6 samples.

How the data were processed

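Raw counts per gene name in 6 mouse libraries were analysed, 3 labelled wild type and 3 labelled intervertebral disc degeneration. Per the labels' protocols, frozen discs were extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The deposited counts were made by featureCounts 2.0.1, per the file headers, from 1 alignment per library, as paired reads with both ends mapped, without chimeric pairs, over exons summed by gene name. No strand option was set, so reads of a gene and an overlapping antisense gene cannot be told apart. Read pairs that map to several places were left out by the tool's default, so genes with close copies (Myh6 and Myh7, for example) are uncertain. The genome build is not given in the headers. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm9 were named without a role. The series' design text speaks of retinal RNA and of transcript-level tools and an ANOVA, and the samples' own labels of the intervertebral disc; groups were taken from the sample labels. A deposited table of the whole series has 12 columns of values under names that no sample label uses, and was not used.

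Rows of the 6 files were identical in name and interval. Counts were used as deposited, and CPM was computed from each library's total over all 53546 rows. Each row's intervals were read as GRCm38 positions and intersected with the exons of GENCODE M21 (bedtools 2.31.1, Python 3.11.15, pandas 2.3.3). A row was in register when at least 90% of its length lay on exons of its own gene. Otherwise it took the name of the GRCm38 gene that held at least 80% of the exon bases under it, with at least 100 bases, and rows of 1 gene were summed. A locus so named can be counted over a small part of its exons, so levels of different genes are not comparable as expression. Lists of tissue markers were therefore compared per kb of covered exon, which lessens this limit without removing it. Levels of 1 gene can be compared between libraries only up to scaling, since CPM uses library totals alone. The TMM factors of the test on rows were 0.864 to 0.94 in wild type 1 to 3 and degeneration 1. They were 1.234 and 1.248 in degeneration 2 and 3, where CPM therefore stands higher than under the scaling of the test. The relabelling by position was chosen after the data were seen. Gene coordinates are those of GENCODE M21 on GRCm38. The coordinates shown for rows named Cebpe and Slc7a8 are as the files give them.

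The main comparison was fixed before the data were examined: edgeR 4.0.16 (R 4.3.3), quasi-likelihood test, TMM scaling, filterByExpr, no covariate, all 6 libraries, Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on the deposited rows as the main result and on the loci. filterByExpr asks for a minimum count level in as many libraries as the smaller group holds, so a gene that reaches it in 2 libraries is not tested. The SE of a log2 fold change was derived from the test statistic. Gene lists (35, written before the data were examined) were tested by camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2, where at least 5 members were tested, and again with an estimated correlation and by fry. Named genes followed a rule fixed before the data were examined. It took the 8 largest changes per direction past the threshold with at least 5 CPM and no overlap of groups. If none passed, it took the 8 smallest p per direction under the same other conditions. It also took a panel of 18 genes, and up to 3 members per list with the smallest p. A further 17 genes, and 8 lists of tissue markers used in the closing section, were chosen after the values were seen. Some results are not reported here.

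Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR, scaling without the 20 most abundant rows, no count filter, a filter at a mean of 1 CPM, the replicate number as a block, limma-trend, and each library left out. Alternatives for FPKM values were not needed, as the files hold counts. Alternatives added after seeing the data were the relabelling by position, the rows in register alone, both without degeneration 1, and the replicate block on loci and on lists by position. The test was tried on simulated counts with the wild type means and spread and 200 changed genes: on 13286 rows it recovered 60% of 2-fold and 100% of 4-fold changes with 12 false calls, and on 5001 loci 69% and 99% with 10 false calls. Library pairs were compared by Pearson's r across rows and by a chi-square over rows with at least 20 counts in the pair. Library totals of 3119215 to 4009562 counts set the floor of 3 counts at 0.748 to 0.962 CPM; floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.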

Results

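RNA-seq libraries were described from C57BL/6 mice, with the intervertebral disc (the fibrous and gelatinous pad between vertebrae) as their labelled source. The labels put 3 libraries in a wild type group and 3 in a disc degeneration group, and do not say how degeneration was brought about or whether each library came from a separate animal. The p-values therefore measure only the spread between these libraries, which may be technical. The total count per library was 4009562, 3576381 and 3317474 in wild type 1 to 3 and 3176108, 3451759 and 3119215 in degeneration 1 to 3. Between 24528 and 26893 of the 53546 rows had a count in a library. A count of 3, taken as the floor of detection, corresponds to 0.748 to 0.962 CPM, a count scaled by its library's total as is usual, and this floor covers counting error only.

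The question the groups pose is which genes differ between discs labelled as degenerated and wild type discs. The 3 libraries labelled degeneration did not share one profile. Egf, which encodes epidermal growth factor, stood at 2621 and 2285 CPM in degeneration 2 and 3, at 20.5 CPM in degeneration 1, and at 9.73, 12.9 and 17.8 CPM in wild type 1 to 3. Lmod2, which encodes leiomodin 2, an actin-binding protein of striated muscle thin filaments, stood at 1656, 1292 and 2005 CPM in wild type 1 to 3 and at 2110 CPM in degeneration 1. In degeneration 2 it had 0.579 CPM and in degeneration 3 it had no count, which allows up to 0.962 CPM. With all 6 libraries Egf had a log2 fold change of 6.57 ± 1.62 (SE) and an adjusted p of 0.233 (edgeR quasi-likelihood test). Without degeneration 1, the log2 fold change was 7.11 ± 0.25 and the adjusted p was 6.5e-09. Over the 8 fits of this locus the adjusted p ran from 6.5e-09 to 0.605. Egf and Lmod2 were singled out after their values were seen.

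Values in the text are given by position. Each row's intervals were read as GRCm38 positions and compared with GENCODE M21 exons, on the assumption that reads had been placed on GRCm38, and most rows had no base on GRCm38 exons of the gene they are named for (49890 rows). Of the 53546 rows, 1740 lay with at least 90% of their length on the exons of the gene they are named for. These rows are called in register. They held 6.03% to 8.35% of the counts of a library, and 1315 of them lay outside the mitochondrial genome and chromosome Y, mostly on chromosome 4 (761 rows) and chromosome 6 (324 rows). Lmod2 (chromosome 6, 24597762 to 24605414, plus strand, 1973 of 1976 exon bases under its own row) is among them, and Egf (chromosome 3, 129677565 to 129755316, minus strand) is not. A further 11501 rows lay over 1 gene for at least 80% of the exon bases they covered and at least 100 bases, and were given that gene's name. Some of these rows, as those named Casp1 and Ryr2, bore that name already. The 13241 rows located in either way made 10913 loci and held 49.8% to 58.7% of the counts of a library. The Wilson 95% intervals of these shares were within 0.055 percentage points.

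The row with the highest count in wild type 1 to 3 and degeneration 1 is named Ttn, with 493483, 476150, 422083 and 434293 counts, and had 22.9% of its length on exons of Ttn, with 6940 bases on Osbpl6, so it met neither rule and is not part of the values given for Ttn. Some rows with high counts, as those named Svil and Flnc, lay on their own gene, and others shared no base with it, of which the following are examples. The row named Ltbp3 held 389476, 369288 and 337097 counts in wild type 1 to 3 and 274664, 407033 and 446653 in degeneration 1 to 3, and 3020 bases of it lay on Malat1, a long non-coding RNA of nuclear speckles. The row named Malat1 itself held 99 to 236 counts. The row named Myh6, for the alpha myosin heavy chain of heart muscle, held 0 counts in every library. The rows named Cebpe and Slc7a8 together held 119572, 124967, 118834 and 129533 counts in wild type 1 to 3 and degeneration 1, against 36 and 25 in degeneration 2 and 3. Their intervals on chromosome 14 overlap exons of Myh6 (54941921 to 54966927), and the row named Slc7a8 also overlaps 397 bases of Myh7, a close paralog. All 37 rows of the mitochondrial genome were in register and had 0 counts in every library.

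**Figure D1:**
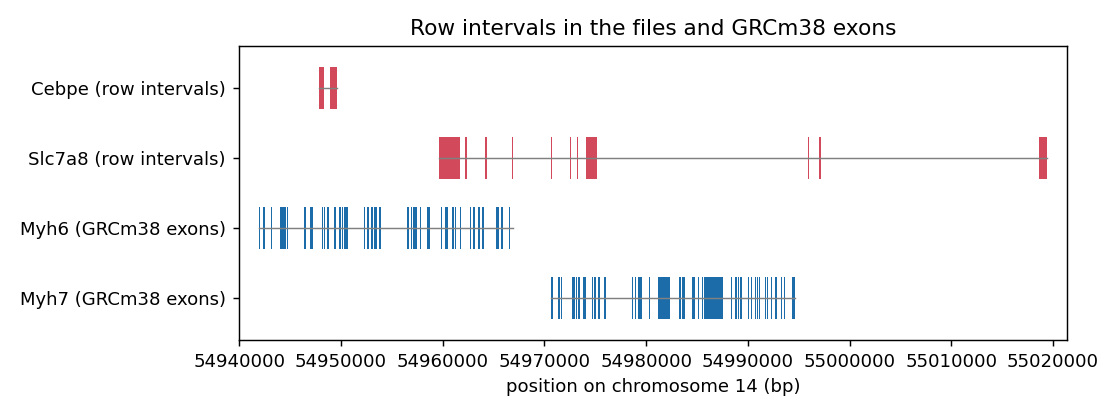
Intervals of the rows named Cebpe and Slc7a8 (red) and GRCm38 exons of Myh6 and Myh7 (blue) by position on chromosome 14 in bp, with thin grey lines joining the parts of 1 row or gene. The row named Cebpe lies within Myh6, and the row named Slc7a8 overlaps exons of both Myh6 (683 bases) and Myh7 (397 bases).

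Genes best known from striated and heart muscle were abundant in wild type 1 to 3 and degeneration 1. These and the genes of the next paragraph were singled out after their values were seen. Myh6, counted over 362 of its 6726 exon bases, stood at 14664, 16395 and 17448 CPM in wild type 1 to 3, at 18993 CPM in degeneration 1, and at 2.03 and 1.60 CPM in degeneration 2 and 3. Ryr2, the calcium release channel of the cardiac sarcoplasmic reticulum, stood at 6012 to 7264 CPM in the first 4 of these libraries and at 12.7 and 17.3 CPM in degeneration 2 and 3. Ttn, the giant sarcomere protein titin, stood at 9337 to 11338 CPM and at 22.0 and 18.9 CPM in the same order. Ckm, the muscle creatine kinase, stood at 466 to 801 CPM and had no count in degeneration 2 and 3. Myl3, a myosin light chain, stood at 1645 to 2596 CPM and at 1.74 and 0.641 CPM, and Trdn, the junctional protein triadin, at 249 to 463 CPM and at 1.74 and 0.641 CPM. For Flnc, filamin C, whose row on chromosome 6 was in register, the values were 2493, 3242 and 1449 CPM in wild type 1 to 3, 1592 CPM in degeneration 1, and 11.6 and 11.9 CPM in degeneration 2 and 3.

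Genes best known from the kidney tubule were abundant in degeneration 2 and 3. Calb1, the calcium-binding protein calbindin, was in register on chromosome 4 (15881264 to 15908064, plus strand) and stood at 1344 and 1047 CPM there, with 0.249 CPM in wild type 1 and no count in wild type 2, wild type 3 and degeneration 1. Lrp2, the endocytic receptor megalin, stood at 2829 and 2030 CPM in degeneration 2 and 3 and at no more than 1.89 CPM elsewhere. Its partner Cubn, cubilin, stood at 1059 and 904 CPM against 6.15 to 8.73 CPM. Egf, given above, has its precursor made in the distal tubule. Slc12a3, the thiazide-sensitive sodium chloride cotransporter, stood at 1440 and 1019 CPM against 13.7 to 20.2 CPM. Slc34a1, a sodium phosphate cotransporter, stood at 1081 and 966 CPM and had no count in the other 4 libraries. Calb1, Lrp2 and Slc34a1 did not meet the count filter of the test with all 6 libraries.

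**Figure D2:**
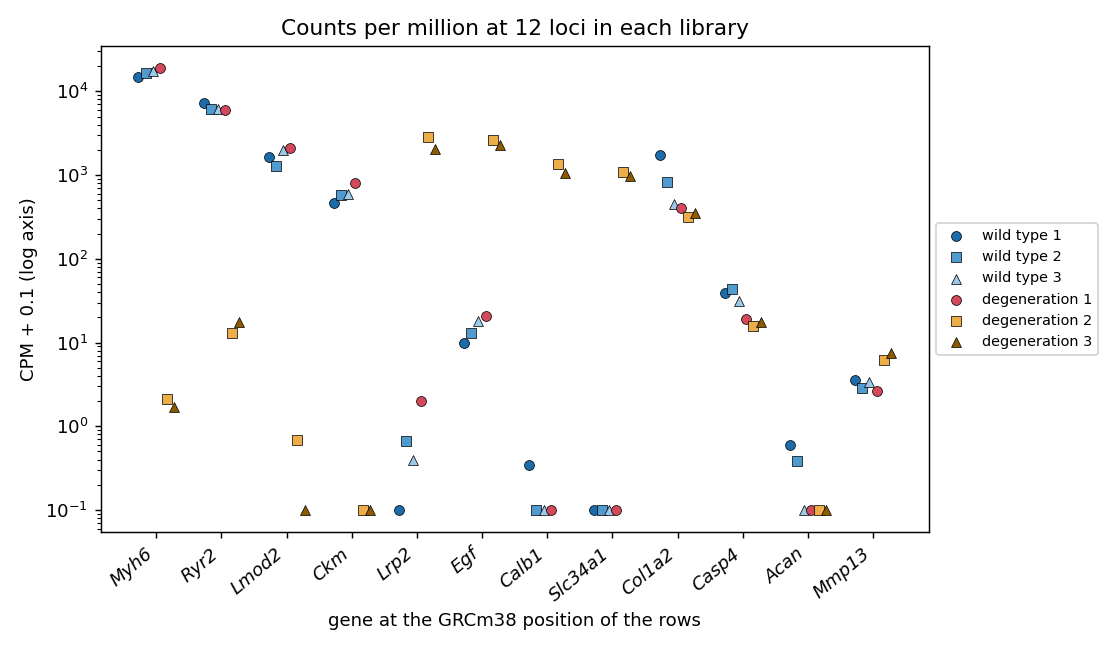
CPM plus 0.1 on a log axis (vertical) at 12 loci named by GRCm38 position (horizontal), with 1 point per library and no averaging; points at 0.1 had no count. Degeneration 1 (red circles) lies with the wild type libraries (blue) from Myh6 to Slc34a1, where degeneration 2 and 3 lie apart, with Egf at 2621 and 2285 CPM.

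The test found 0 of 14967 rows at an adjusted p under 0.05 with edgeR's quasi-likelihood test, and 2596 rows at an unadjusted p under 0.05. limma-trend also called 0 rows, and DESeq2 called 969 of 17476 rows, 859 higher and 110 lower in degeneration. Without degeneration 1 the edgeR count was 8703 of 17272 rows, 4477 higher and 4226 lower. After relabelling by position it was 0 of 5434 loci, with 1064 at an unadjusted p under 0.05, and 3162 of 5969 loci without degeneration 1. In simulated counts with the spread of the wild type libraries, the same test on rows recovered 60% of 2-fold and 100% of 4-fold changes. The common dispersion was 0.1727 with all 6 libraries and 0.0229 without degeneration 1.

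Across the 20132 rows with a mean of at least 1 CPM, the wild type libraries correlated with each other at 0.966 to 0.979 (Pearson's r of log2(CPM + 1), across rows, which are not independent replicates). Degeneration 1 correlated with wild type 1 to 3 at 0.967, 0.963 and 0.977 and with degeneration 2 and 3 at 0.688 and 0.686. Degeneration 2 and 3 correlated with each other at 0.979. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 3.7, between degeneration 2 and 3.

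**Figure D3:**
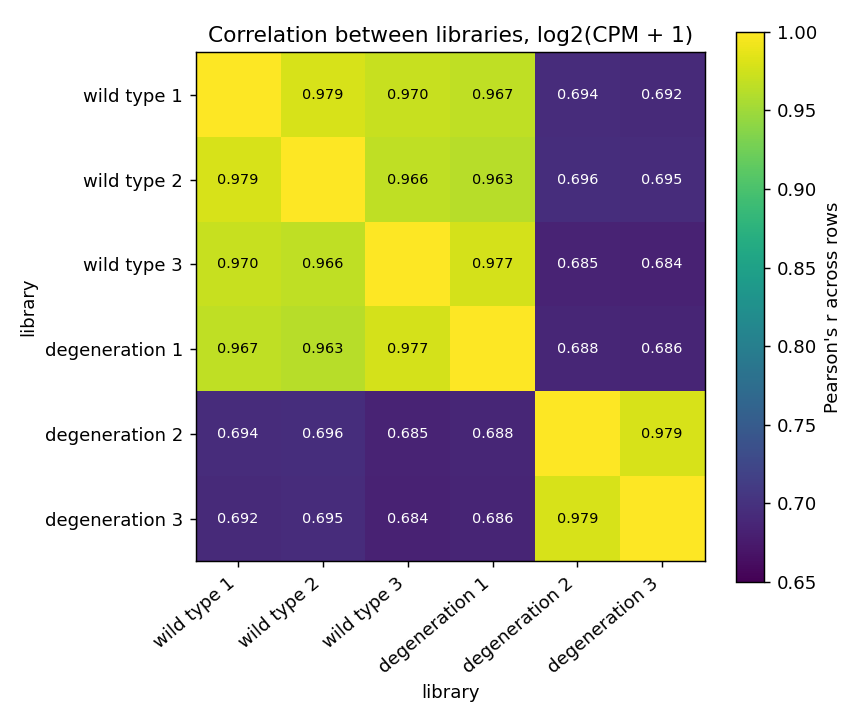
Pearson's r of log2(CPM + 1) across rows for each pair of the 6 libraries, by colour and number. Degeneration 1 has r of 0.963 to 0.977 with the wild type libraries and 0.688 and 0.686 with degeneration 2 and 3.

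Casp1, Casp4 and Gsdmd of the inflammasome list were lower in all 3 degeneration libraries, degeneration 1 included, than in any wild type library. So was Oas1a of the interferon response list. None of them passed the threshold in edgeR with all 6 libraries. DESeq2 was run on the deposited rows alone and is given with the named rows below. Casp1, the caspase that matures interleukin 1 beta, stood at 19.6 ± 0.763 CPM in wild type and 7.59 ± 0.569 CPM in degeneration (mean ± SD, n = 3 each). It had the smallest p among the rows that the rule for named genes took, with a log2 fold change by position of -1.56 ± 0.24 (SE) and an adjusted p of 0.233 (edgeR). Casp4, which senses intracellular lipopolysaccharide, was in register on chromosome 9 (5308828 to 5336783) and stood at 37.9 ± 6.35 CPM in wild type and 17.5 ± 1.79 CPM in degeneration. Gsdmd, the pore-forming protein gasdermin D that these caspases cleave, stood at 25.6 ± 3.01 CPM and 11.5 ± 1.89 CPM. Of the 4 tested members of the inflammasome list, 0 passed over all loci tested and 3 (these) passed when adjusted over the list alone. The remaining tested member, Nek7, stood at 39.4 to 48.9 CPM in wild type and 37.5 to 51.9 CPM in degeneration. The list had too few tested members for the list test with all 6 libraries. With 1 library left out it had enough in 4 fits, where it was lower in degeneration (camera adjusted p from 0.0023 to 0.0115 with the preset correlation, the only one run there). Without degeneration 1 all 3 genes fell, with adjusted p of 7.8e-05, 9.3e-05 and 0.00016 (edgeR), in a fit that set Myh6 at 14664 to 17448 CPM in wild type against 2.03 and 1.60 CPM, and Egf at 9.73 to 17.8 CPM against 2621 and 2285 CPM, and in which 3162 of 5969 loci passed. Their adjusted p over 8 fits reached 0.605. Counts adjusted over a list alone, here and below, are not corrected over the 35 lists. Since 1064 of 5434 loci had an unadjusted p under 0.05, such counts do not show a change particular to a list. By CPM the macrophage markers C1qc and Lyz2 were likewise lower in every degeneration library than in any wild type library. The macrophage markers Csf1r, Mrc1 and Aif1 were not. For C1qc this rests on 16.3 CPM in wild type 3 against 16.1 CPM in degeneration 1. The TMM factors of these libraries, 0.908 and 0.864, can undo so small a gap. Of the interferon response list, 4 members were tested, 0 passed over all loci, and 2 (Oas1a and Oasl2) passed when adjusted over the list alone. Oas1a, which activates RNase L, stood at 21.7 ± 5.04 CPM in wild type and 12.4 ± 0.951 CPM in degeneration (n = 3 each). The other members did not part the groups: Ifit1 stood at 54.4, 42.2 and 84.4 CPM in wild type 1 to 3 and at 40.9, 59.1 and 88.8 CPM in degeneration 1 to 3, Ifit2 at 8.73, 12.6 and 14.2 CPM and at 7.24, 13.9 and 23.4 CPM, and Oasl2 at 15.0, 19.0 and 18.7 CPM and at 10.1, 11.6 and 15.7 CPM. The summed CPM of the 4 was 98.8, 101 and 134 in wild type 1 to 3 and 69.6, 97.3 and 141 in degeneration 1 to 3.

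Collagen and fibroblast genes varied within the wild type group as well as between the groups. Col1a2, a chain of type I collagen in register on chromosome 6 (4504814 to 4541544), stood at 1749, 832 and 448 CPM in wild type 1 to 3 and at 408, 317 and 353 CPM in degeneration 1 to 3. Its log2 fold change was -1.66 ± 0.54 (SE) with an adjusted p of 0.233, and -1.98 ± 0.44 with an adjusted p of 0.0031 without degeneration 1 (edgeR). Without wild type 1 it was -1.06 ± 0.44 with an adjusted p of 0.438, and over its 8 fits the adjusted p ran from 0.0031 to 0.605. Of the 6 tested members of the fibrosis list, 0 passed over all loci and 3 (Col1a1, Col5a2 and Fn1) passed when adjusted over the list alone. Without degeneration 1 all 6 fell, in the same fit in which Myh6 stood at 14664 to 17448 CPM against 2.03 and 1.60 CPM. Of the 8 tested members of the annulus and tendon fibroblast list, 0 passed over all loci and 4 passed when adjusted over the list alone, among them Col5a1, a fibrillar collagen chain, and Cilp, a cartilage and fibrous tissue matrix protein. Without degeneration 1, 9 were tested, of which 6 fell and 1 rose. The summed CPM of this list's located members was 3066, 1528 and 973 in wild type 1 to 3, and 923, 603 and 671 in degeneration 1 to 3.

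The endothelial markers Pecam1, Eng and Tek had lower values in all 3 degeneration libraries than in any wild type library. They did not pass the threshold in edgeR with all 6 libraries. Emcn did not part the groups, at 2.99, 4.47 and 6.93 CPM in wild type 1 to 3 and 5.35, 5.50 and 5.13 CPM in degeneration 1 to 3. Of 6 tested members, 0 passed over all loci, 3 (Eng, Tek and Pecam1) passed when adjusted over the list alone, and 5 fell without degeneration 1, where Myh6 differed as given above. Their summed CPM was 1163, 1201 and 1020 in wild type 1 to 3, and 750, 416 and 447 in degeneration 1 to 3. Pecam1, an adhesion molecule of endothelial junctions, stood at 474 ± 48.5 CPM in wild type and 231 ± 81.3 CPM in degeneration (n = 3 each). By camera with its preset correlation, 3 of the 7 lists with enough located members were lower in degeneration: fibrosis (adjusted p = 0.00433), endothelium (adjusted p = 0.00433) and annulus and tendon fibroblast (adjusted p = 0.0164). None of the 3 passed with an estimated correlation (adjusted p = 0.369 for each). By fry the adjusted p was 0.0878 for each of them, and 0.0396 for the matrix protease list, whose members move, on balance, lower. Without degeneration 1 the preset adjusted p was 0.0482 for fibrosis, 0.0136 for endothelium and 0.145 for annulus and tendon fibroblast, which also missed the threshold without wild type 1 (0.0801). Over all settings tried the adjusted p ran from 9.14e-05 to 0.555 for fibrosis, from 0.0023 to 0.555 for endothelium and from 0.00284 to 0.555 for annulus and tendon fibroblast. Under the names as deposited, 0 of 22 lists passed by camera and 0 by fry, with 2 and 6 lists at an unadjusted p under 0.05; most of those names are not those of the GRCm38 exons under the rows, so no single list is given under them.

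Nuclear genes of oxidative phosphorylation were highest in degeneration 1 and lowest in degeneration 2 and 3. Of 7 tested members 0 passed, also when adjusted over the list alone, and all 7 fell without degeneration 1 (camera adjusted p = 0.00625, and 0.555 with an estimated correlation), in the fit in which Myh6 stood at 14664 to 17448 CPM against 2.03 and 1.60 CPM. With all 6 libraries the camera adjusted p was 0.109. Their summed CPM was 3956, 3616 and 3752 in wild type 1 to 3, 5325 in degeneration 1, and 2233 and 1662 in degeneration 2 and 3. Of 8 tested hypoxia and glycolysis genes 0 passed, also over the list alone, and 4 rose and 2 fell without degeneration 1. Adm, the vasodilator peptide adrenomedullin, stood at 12.5 to 18.6 CPM in wild type and degeneration 1 and at 83.1 and 107 CPM in degeneration 2 and 3. Of 6 tested matrix protease genes 0 passed over all loci and 3 (Ctsl, Adamts9 and Mmp3) passed when adjusted over the list alone; without degeneration 1, 1 rose and 3 fell.

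Cartilage matrix genes were low where located. The summed CPM of the 6 located cartilage matrix genes (Acan, Col9a3, Col11a2, Cnmd, Chad and Sox5) was 31.7, 28.0 and 28.9 in wild type 1 to 3 and 22.0, 32.7 and 42.6 in degeneration 1 to 3. Acan, the large aggregating proteoglycan of cartilage, was counted over 1158 of its 7469 exon bases and stood at 0.499 and 0.280 CPM in wild type 1 and 2, under the floor, with no count in the other libraries. All rows sharing a base with its exons, 5022 bases in all, held 3.49, 2.80 and 1.81 CPM in wild type 1 to 3 and 1.89, 0.290 and 0 CPM in degeneration 1 to 3, so its level over those bases can lie above the floor in 4 libraries. Krt19, a keratin of notochordal nucleus pulposus cells, had no count over 156 exon bases. Of the 18 panel genes chosen before the data were examined, 6 were located: Acan, Krt19, Mmp3, Mmp13, Col1a1 and Cdkn1a. The other 12 (Col2a1, Col10a1, Sox9, Tbxt, Shh, Adamts4, Adamts5, Il1b, Il6, Tnf, Cdkn2a and Runx2) have no value here, because no row met the position rule for them. All rows sharing a base with Col2a1 exons, 636 of 9243 bases, held 6.24, 4.19 and 4.52 CPM in wild type 1 to 3. In degeneration 1 to 3 they held 3.78, 9.27 and 12.2 CPM, which bounds Col2a1 over those bases only. Such rows held 1.16 to 3.91 CPM for Tnf (589 bases) and no count for Il6 (43 bases). Mmp13, a collagenase in register on chromosome 9 (7272514 to 7283331), stood at 3.49, 2.80 and 3.32 CPM in wild type 1 to 3 and at 2.52, 6.08 and 7.37 CPM in degeneration 1 to 3 (adjusted p = 0.469, edgeR). Mmp3, stromelysin 1, in register on chromosome 9 (7445822 to 7455975), stood at 25.7, 22.1 and 7.54 CPM in wild type 1 to 3, at 4.72 and 0.962 CPM in degeneration 1 and 3, and had no count in degeneration 2. Cdkn1a, the cell cycle inhibitor p21, stood at 91.0, 94.8 and 19.6 CPM in wild type 1 to 3 and at 17.9, 7.24 and 8.34 CPM in degeneration 1 to 3. Col1a1 stood at 629, 284 and 146 CPM and at 128, 54.2 and 67.6 CPM in the same order. All 4 had adjusted p above the threshold with all 6 libraries, and without degeneration 1 the call of Mmp3, Cdkn1a and Col1a1 changed (adjusted p of 0.00019, 0.00067 and 0.00058, edgeR).

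No row passed in edgeR, so the rule for named genes turned to rows without overlap of groups and with at least 5 CPM. Of these it took the 8 rows with the smallest p in each direction. Their log2 fold changes ran from -1.80 to 2.66, each with an adjusted p of 0.258 (edgeR). Most of them passed with DESeq2. Of these 16 rows 1 (Casp1) shared bases with the exons of the gene it is named for, and 8 were located. The row named Slc29a2 lay over Tmem151a, at 1.09 ± 0.173 CPM in wild type and 8.47 ± 4.81 CPM in degeneration (n = 3 each). The row named Cer1 lay over Zdhhc21, a palmitoyltransferase, at 13.2 ± 0.675 CPM and 29.1 ± 6.35 CPM. The row named Slc26a9 lay over Rab7b, a late endosomal GTPase, at 16.3 ± 3.34 CPM and 5.34 ± 0.596 CPM. In each of these 3 loci the groups did not overlap, which the rule required. The groups did not overlap in 2967 of all 14967 rows tested (19.8%). Chance gives 10% for 6 exchangeable libraries, which these are not, since degeneration 2 and 3 stand apart, so the share is not read as an excess.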

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

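All tests of explanations below were chosen after the results they bear on were seen, except the counts over other splits of the libraries.

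Counts of many genes stand under rows named for other genes. A candidate explanation is that reads were placed on GRCm38 and counted with intervals of another build: rows with at least 50% of their length on GRCm38 exons of other genes (2491 rows) held at least 7.8 times as many counts per kb, in each library, as the 33826 rows off all GRCm38 exons, and 641 pairs of rows over 1 gene had a median r over libraries of 0.864, against 0.282 for random pairs. Low depth cannot move intervals, and 49890 of the 53546 rows shared no base with exons of their own gene, whatever their counts. This argues against depth as the cause of where the names stand. Whether depth plays a further part stays open. Of coding rows with no base on their own exons, 33.8% reached 10 CPM against 64.9% of coding rows in register, a ratio of 0.52. It met neither bound (0.8 if depth, 0.5 if not), and both were written before that share was computed. The test was taken as the deciding one after its value was known. A later test, the share of a locus's counts in the row of its own name (median 9.11% over 584 loci), decides nothing, since those loci were chosen for lying off that row. No biological explanation was tested, and which build the intervals come from stays open.

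Degeneration 2 and 3 stand apart from degeneration 1 and the wild type libraries. Whether single labels were exchanged between the groups stays open. The wild type libraries correlated at 0.966 or more with each other and at most at 0.696 with degeneration 2 or 3, which restates the pattern. An exchange of degeneration 1 with a wild type library would leave no trace, as degeneration 1 correlated with wild type 3 at 0.977. An exchange moves names and not profiles. Wild type 1 to 3 and degeneration 1 correlated with each other at 0.963 or more, and with degeneration 2 and 3 at 0.684 to 0.696. Undoing an exchange would leave the same libraries apart. This argues against such an exchange as the cause of the pattern. RNA of other tissues, not the same in all libraries, may account for the pattern but stays open: the cardiomyocyte list (6 located, led by Myh6, Ttn and Ryr2) summed to 35743, 37016, 38791 and 39439 CPM in wild type 1 to 3 and degeneration 1 and to 40.9 and 39.1 CPM in degeneration 2 and 3, the kidney epithelium list (14 located, led by Lrp2 and Egf) to 57.0 to 72.7 CPM and to 11872 and 9586 CPM, and per kb of covered exon the highest list was at least 29.9 times the next among the 8 tissue lists chosen later (59.1 times on sums) but 3.9 times at the lowest once the 17 tissue and cell type lists fixed before were added, short of the bound of 10 (next were skeletal muscle with Ttn, erythroid and nucleus pulposus). Disc tissue that had degenerated in 2 of 3 libraries stays open too: per kb of covered exon the cartilage list (6 of 20 located) came to at most 1.96% of the highest tissue list (0.44% on sums) and the annulus list (12 of 16 located) to at most 4.56%, but in degeneration 2 and 3 the hypertrophic cartilage list (4 located, led by Pth1r) came to 13.3% and 12.8% and the nucleus pulposus list (7 located, led by Car12, Cd24a and Krt8, with Cdh2 at 5.50 and 5.45 CPM against 196 to 281 elsewhere, Krt19 without a count and Noto at no more than 0.321 CPM) to 21.1% and 25.8%, over the bound of 10%, while no disc list passed 2.78% in the other 4 libraries. The hypertrophic cartilage share rests on Pth1r, at 597 and 462 CPM of the list's 605 and 469 in degeneration 2 and 3. The nucleus pulposus share rests on Car12, Cd24a and Krt8. In degeneration 2 they stood at 407, 352 and 127 CPM of the list's 894. Which tissue these genes came from was not tested. The ratio of the kidney epithelium list to the nucleus pulposus list therefore cannot tell whether they mark separate tissues. The skeletal muscle list shares Ttn with the cardiomyocyte list, so their ratio does not compare separate genes. In wild type 3 the next list was erythroid, at a ratio of 5.6, and it shares no located member with the cardiomyocyte list. Sums of the other lists chosen later were skeletal muscle without Ttn, Ckm and Neb (3.85 to 12.3 CPM), liver (1.00 to 42.0), intestine (3.78 to 177), lung (5.21 to 110), brain (23.8 to 55.3) and retina (4.72 to 10.4). Labels that are not a library's own and tissue taken along at dissection stay open. Whether whole groups were exchanged stays open too, but that would also move names alone and leave the same libraries apart.

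With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled groups gave 0 rows past the threshold and the highest other split 0, so all 10 were as large; at an unadjusted p under 0.05 the labelled groups gave 2596 rows and the highest other split 2594. The 4 splits that kept degeneration 2 and 3 together gave 2178 to 2596 such rows and the other 6 gave 30 to 200, which points to a structure of the libraries other than the labels. For lists by position, the labelled groups gave 3 and the highest other split 4, and 2 of the 10 splits gave at least 3.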

How the results depend on the processing

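Among settings fixed before the data were examined, the count of changed rows was 0 in all but DESeq2 (969) and the fit without degeneration 1; leaving out 1 library each gave 0 to 8703, and the 8703 came from leaving out degeneration 1. With the replicate number as a replicate block the count was 0, with 1825 rows at an unadjusted p under 0.05; the numbers are not said to pair animals, and deviations of same-numbered libraries correlated at -0.08, 0.099 and -0.122, so only wild type 2 and degeneration 2 correlated best with their own number. The block changed no call, and none by position, where it was added after seeing the data (0 loci, 678 at an unadjusted p under 0.05, and 3 lists with the preset correlation). Alternatives meant for FPKM values were not run, since counts were used. Settings chosen after seeing the data gave 0 for rows in register alone (297 without degeneration 1) and 0 for loci (3162 without degeneration 1). Without degeneration 1 the common dispersion was 0.0229 against 0.1727 and fold changes moved as well; for that fit and for DESeq2 the cause was not tested. The count of lists was 0 in all settings fixed before the data were examined. By position it was 3 with the preset correlation, 0 with an estimated one, 1 by fry, and with 1 library left out 3, 4 (without wild type 2 or degeneration 2) or 5 (without degeneration 3), against 0 under the names as deposited. Named rows kept their direction in all alternatives, as did named loci; 30 of 208 values of named rows and 16 of 119 of named loci passed the threshold, in DESeq2 or without degeneration 1. At this depth, values under 0.748 to 0.962 CPM were not detectable.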

Other observations

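Within the wild type group some loci differed widely between libraries. Among 1962 loci with a mean of at least 50 CPM, Hbb-bs, a beta globin chain of red cells, stood at 283, 1563 and 4245 CPM in wild type 1 to 3 and at 1724, 135 and 105 CPM in degeneration 1 to 3. Alas2, the erythroid enzyme of heme synthesis, stood at 11.7, 38.0 and 55.2 CPM in wild type 1 to 3. Postn, the matrix protein periostin, stood at 209, 56.8 and 22.6 CPM and at 22.0, 2.03 and 3.21 CPM. Pdk4, which inhibits pyruvate dehydrogenase and was in register on chromosome 6, stood at 1258, 1021 and 295 CPM and at 474, 87.5 and 95.2 CPM. A small nuclear RNA gene on chromosome 18, Gm26244, in register over all 164 bases, stood at 91.0, 5104 and 58.2 CPM and at 28.3, 1188 and 47.8 CPM. Apart from Alas2, of the erythroid list, these loci and those of the next paragraph were taken after their values were seen, from the 20 with the highest ratio between wild type libraries.

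Wild type 3 and degeneration 1, the closest pair across the groups (r = 0.977), lay near each other in several of these loci, in some of them together with degeneration 2 and 3. Per3, a repressor of the circadian clock, stood at 76.9 and 66.7 CPM in that pair and at 24.7 and 12.3 CPM in wild type 1 and 2, with 64.3 and 75.02 CPM in degeneration 2 and 3. Nr1d2, a nuclear receptor of the same clock, stood at 124 and 102 CPM and at 58.6 and 41.1 CPM in the same order, with 79.4 and 105 CPM in degeneration 2 and 3. Myom2, a protein of the sarcomere M band, stood at 3324 and 3053 CPM and at 1148 and 809 CPM, with 61.4 and 52.9 CPM in degeneration 2 and 3. Atcay stood at 300 and 277 CPM and at 61.6 and 69.3 CPM, with 0.869 and 0.321 CPM in degeneration 2 and 3.

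Of the lists not described above, macrophage markers had 5 tested members and the others 4 or fewer, and 0 members passed over all loci with all 6 libraries (edgeR). Of the macrophage markers (0 passed over all loci and 0 when adjusted over the list alone; camera adjusted p = 0.109, and from 0.0385 without degeneration 3 to 0.555 over all settings), the summed CPM was 269, 225 and 162 in wild type 1 to 3 and 162, 135 and 133 in degeneration 1 to 3. Of the osteoclast list, Atp6v0d2, a subunit of the vacuolar proton pump, was in register on chromosome 4. It stood at 247 and 215 CPM in degeneration 2 and 3 and at 0.315 to 7.98 CPM elsewhere. Nfatc1 of the same list went the other way, at 11.971, 11.744 and 8.742 CPM in wild type 1 to 3. In degeneration 1 to 3 Nfatc1 stood at 7.871, 3.766 and 5.771 CPM. Calcr, also of this list, stood at 3.187 and 3.527 CPM in degeneration 2 and 3 and had no count elsewhere. Of the hypertrophic cartilage list, Pth1r, the parathyroid hormone receptor, stood at 597 and 462 CPM in degeneration 2 and 3 and at 19.0 to 35.9 CPM elsewhere. Of the nucleus pulposus list, Cdh2, N-cadherin, stood at 196 to 281 CPM in wild type and degeneration 1 and at 5.50 and 5.45 CPM in degeneration 2 and 3, while Car12, a carbonic anhydrase, stood at no more than 0.998 CPM and at 407 and 382 CPM. Immediate early genes, read as a sign of handling, summed to 65.8, 87.8 and 38.6 CPM in wild type 1 to 3 and 41.9, 58.2 and 72.1 CPM in degeneration 1 to 3.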
